A study of Mus musculus with 9 samples.

How the data were processed

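RNA was measured by sequencing in LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive cells) sorted from the bone marrow of parabiotic mice, in 9 libraries. Per the labels' protocols, RNA was isolated with a low-input kit, cDNA was amplified with SMART-Seq v4 and libraries were made with Nextera XT, a chemistry that does not mark strand. Reads of overlapping or antisense genes are therefore not separated by strand. The submitters' processing notes name mm10, CASAVA, RSEM 1.3.1 and limma with no role or order. The annotation release, the scaling method and the gene filter are not given in the sources used here.

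The deposited table holds 14461 Ensembl mouse genes in 9 columns, and its unit is a normalised signal, not counts. In each column 100% of the deposited values are (a number with 2 decimals + 0.5) multiplied by a constant of that column, within a tolerance of 0.001 of the last decimal step. This is the form of an estimated count with the offset used by limma's voom, divided by a scaled library size. The deposited signal values sum to between 913996 and 1134420 per column. From the smallest value of each column, estimated counts were recovered: they totalled 14065855 to 27012345 per library. The smallest of the genes' highest values is 1.003. PCR reads without molecular identifiers are not independent molecules, so these depths describe counting error only. A count of 0 corresponds to a deposited value of 0.0182 to 0.0376, depending on the library.

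Groups were taken from the sample labels: 3 libraries each were labelled circulating, irradiated and endogenous. The design, the gene lists and the rule for named genes were fixed before the data were examined. The planned count-based test was replaced, because the table holds normalised values, by the alternative written in the same plan: limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with robust moderation and all 9 libraries in one fit without covariates. A gene was tested if its value was at least 1 in at least 3 libraries, which left 13771 genes. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The comparisons were circulating against endogenous, circulating against irradiated, irradiated against endogenous, and circulating against the mean of the other groups. Positive log2 values mean higher in the first group named. Per the labels, the titles give circulating and irradiated libraries of the same number a common code and the endogenous libraries codes of their own. A second code, LSK1 or LSK2, is shared by circulating and endogenous libraries and differs in irradiated libraries. The labels do not say what either code stands for, so the fit has no block and pairing stays open. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

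Gene lists with at least 5 tested members (38 lists) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same lists were tested with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance in one direction. Named genes were, per pairwise comparison, the 10 largest rises and the 10 largest falls among called genes with an average log2 value of at least 2 and groups that did not overlap. Predicted loci, pseudogenes, immunoglobulin and T cell receptor segments and mitochondrial genes were left out of that ranking. Up to 4 called members of each list described were added, or up to 4 uncalled members as values, together with Ly6a, Kit, Cd34, Flt3, Ptprc, Cxcr4 and Cxcr2. For the contrast with the mean of the other groups, 5 took the place of 10. Some genes that this rule selects are not reported here. Symbols and coordinates came from the GENCODE annotation of GRCm38, the assembly that mm10 names. Of the deposited genes, 14405 matched a symbol and 56 did not.

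The fit was tested on simulated data with 200 genes changed 2-fold or 4-fold among 13771, in 20 simulations per comparison. With equal spread in the groups, 5.41% of calls were false for circulating against endogenous, 5.35% for circulating against irradiated, 4.12% for irradiated against endogenous and 5.23% for the contrast with the mean. With the spread that each group showed, these became 10.9%, 7.05%, 0% and 20.3%, because the fit shares one estimate of spread while the circulating libraries varied most. With sample weights they were 4.61%, 6.33%, 5.46% and 6.93%. At the spread of each group, 42.1% of 2-fold and 77.3% of 4-fold changes were recovered for circulating against endogenous. For circulating against irradiated these were 44.8% and 76.3%. Each gene was drawn independently in these simulations, without genes that move together in a library. The rates therefore describe the simulated data and need not hold for the real calls.

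Alternatives covered the scaling, the filter, limma-voom on the recovered estimated counts, quality weights, moderation, a test against a fold of 1.5, fits of only the groups compared, the replicate number as a block, and each library left out in turn. Pseudocounts, sample weights, thinning to the shallowest library, removal of GC content and transcript length trends (known for 99.64% of tested genes) removal of genes within 20 Mb of Ptprc and a block by the code in the titles were added after seeing the data. No replicate pair within a group agreed within sampling noise: chi-square per gene was 45.05 to 138.7.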

Results

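The transcriptomes of LSK cells were measured in bone marrow of parabiotic mice, which are surgically joined so that they share a circulation. LSK cells are the immature blood-forming fraction that lacks lineage markers and carries Sca-1 (gene Ly6a) and c-Kit (gene Kit). The series design describes a study of LSK cells that had circulated to the marrow of an irradiated parabiotic mouse. The 9 libraries fell into 3 groups of 3, labelled circulating, irradiated and endogenous. The strain label was C57BL/6 for circulating and irradiated cells and B6SJL CD45.1 for endogenous cells. The label thus changes together with the group in comparisons with endogenous cells. Whether it describes the origin of the sorted circulating cells stays open, given the values near Ptprc reported below. If they came instead from CD45.1 animals like the endogenous cells, strain would differ between circulating and irradiated cells, not between circulating and endogenous cells. Recovered depth ran from 14065855 estimated counts in circulating replicate 2 to 27012345 in irradiated replicate 2. All values below are deposited normalised values, that is, estimated counts divided by a scaled library size, as mean ± SD with n = 3. Positions are in GRCm38.

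The circulating libraries varied most between replicates. The median SD of a gene was 0.382 log2 units in circulating cells, 0.262 in endogenous cells and 0.213 in irradiated cells. The first principal component, with 33.6% of the variance, ran from the endogenous libraries (scores -37.7 to -33.3) through the irradiated libraries (-10.3 to 2.32) and circulating replicate 1 (-1.01) to circulating replicates 3 (46.3) and 2 (72.1). The second, with 19.2%, parted circulating replicate 2 (51.8) from circulating replicate 3 (-51.3). The third, with 12%, set circulating replicate 1 (55.1) apart from all other libraries. Transcripts of the gate were present in all groups: Ly6a stood at 137 ± 9.21 in circulating, 174 ± 23.9 in irradiated and 180 ± 12.8 in endogenous cells, and did not pass the test between any pair of groups. Ptprc, which encodes CD45, stood at 583 ± 115, 486 ± 32.1 and 590 ± 28.3 in the same order, and did not pass either. Of 10 measured sorting markers, 1 rose, 1 fell and 8 did not pass in circulating against endogenous cells, with 1 rising and 6 falling when adjusted over the list alone (median -0.51, camera adjusted p = 0.039, and adjusted p = 0.41 with an estimated correlation). That call ended without circulating replicate 3 (adjusted p = 0.13), endogenous replicate 1 (0.058) or endogenous replicate 2 (0.076).

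Circulating LSK cells were first compared with endogenous LSK cells. Genes of granulocyte and monocyte progenitors were higher in circulating cells and genes associated with haematopoietic stem cells (HSC) were lower. Of 17 measured members of the myeloid progenitor list, 9 rose, 0 fell and 8 did not pass the test, with 13 rising when adjusted over the list alone. Ms4a3, a marker of granulocyte-monocyte progenitors, was 688 ± 361 in circulating and 46.8 ± 10.1 in endogenous cells (log2 fold change 3.72, SE 0.36, limma adjusted p = 0.0011). Ctsg, which encodes the granule protease cathepsin G, was 1710 ± 886 against 125.0 ± 20.4. Elane, which encodes neutrophil elastase, was 3434 ± 1792 against 246 ± 81.1, and Prtn3, encoding proteinase 3, was 1142 ± 607 against 149 ± 23.7. Fcgr3, an Fc receptor for immunoglobulin G, was 238 ± 125 against 17.1 ± 7.12. The list's median log2 fold change was 2.74 (camera adjusted p = 7.8e-13, and adjusted p = 0.26 with an estimated correlation).

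Of 21 measured HSC-associated genes, 9 fell, 0 rose and 12 did not pass, with 12 falling when adjusted over the list alone. Hlf, a transcription factor of stem cells, was 56.5 ± 19.0 in circulating and 195 ± 12.3 in endogenous cells (log2 fold change -1.82, SE 0.21, limma adjusted p = 0.0026). Procr, the endothelial protein C receptor, was 23.1 ± 6.08 against 65.9 ± 13.6, and Ndn, which encodes the growth suppressor necdin, was 1.80 ± 1.52 against 23.6 ± 4.79. The median log2 fold change was -0.91 (camera adjusted p = 8.4e-08), and this was the only one of the 15 lists called in this comparison that held with an estimated correlation (adjusted p = 0.047). With fry, 7 of the 15 were called in the same direction, this list among them (fry adjusted p = 0.00054). Kit itself fell from 879 ± 137 to 379 ± 45.13 (log2 fold change -1.20, SE 0.13, limma adjusted p = 0.0026). Cd34 was 1047 ± 325 against 1557 ± 39.8 and Flt3 495 ± 235 against 773 ± 118, and neither passed the test.

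Cell cycle genes rose in circulating cells. Of 24 measured genes of G2/M and mitosis, 19 rose and 5 did not pass, with 23 rising when adjusted over the list alone. The median log2 fold change was 0.95 (camera adjusted p = 1.2e-18, and adjusted p = 0.26 with an estimated correlation). Birc5, which encodes survivin, was 191 ± 27.7 against 79.3 ± 7.80, Ccnb2, a mitotic cyclin, 285 ± 28.7 against 140 ± 5.25, and the mitotic kinase gene Plk1 145 ± 52.9 against 38.1 ± 3.48. Of 26 genes of G1/S and DNA replication, 12 rose and 14 did not pass, with 16 rising when adjusted over the list alone (median 0.50, camera adjusted p = 5.8e-10, and adjusted p = 0.14 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was 470 ± 103 against 186 ± 1.45.

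Respiratory chain genes encoded in the nucleus rose as well: 20 of 35 passed and 15 did not, with 31 rising when adjusted over the list alone (median 0.52, camera adjusted p = 1.3e-17, and adjusted p = 0.23 with an estimated correlation). Examples are Ndufa1 at 159 ± 15.9 against 82.27 ± 6.995 and Cox5b at 215 ± 1.42 against 136 ± 7.69. Of 17 genes of the unfolded protein and integrated stress response, 6 rose and 11 did not pass, with 8 rising and 1 falling when adjusted over the list alone (median 0.46, camera adjusted p = 0.0032, and adjusted p = 0.41 with an estimated correlation). Hspa5, an endoplasmic reticulum chaperone, was 1425 ± 534 against 599 ± 30.6. Of 30 type I interferon response genes, 11 fell, 0 rose and 19 did not pass, with 15 falling when adjusted over the list alone (median -0.78, camera adjusted p = 5.7e-09, and adjusted p = 0.14 with an estimated correlation). Ifi44 was 35.4 ± 10.98 against 112 ± 2.25, Ifit1 9.45 ± 1.11 against 35.6 ± 7.41, and Irf9, a transcription factor of interferon signalling, 111 ± 3.86 against 177 ± 9.46.

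**Figure D1:**
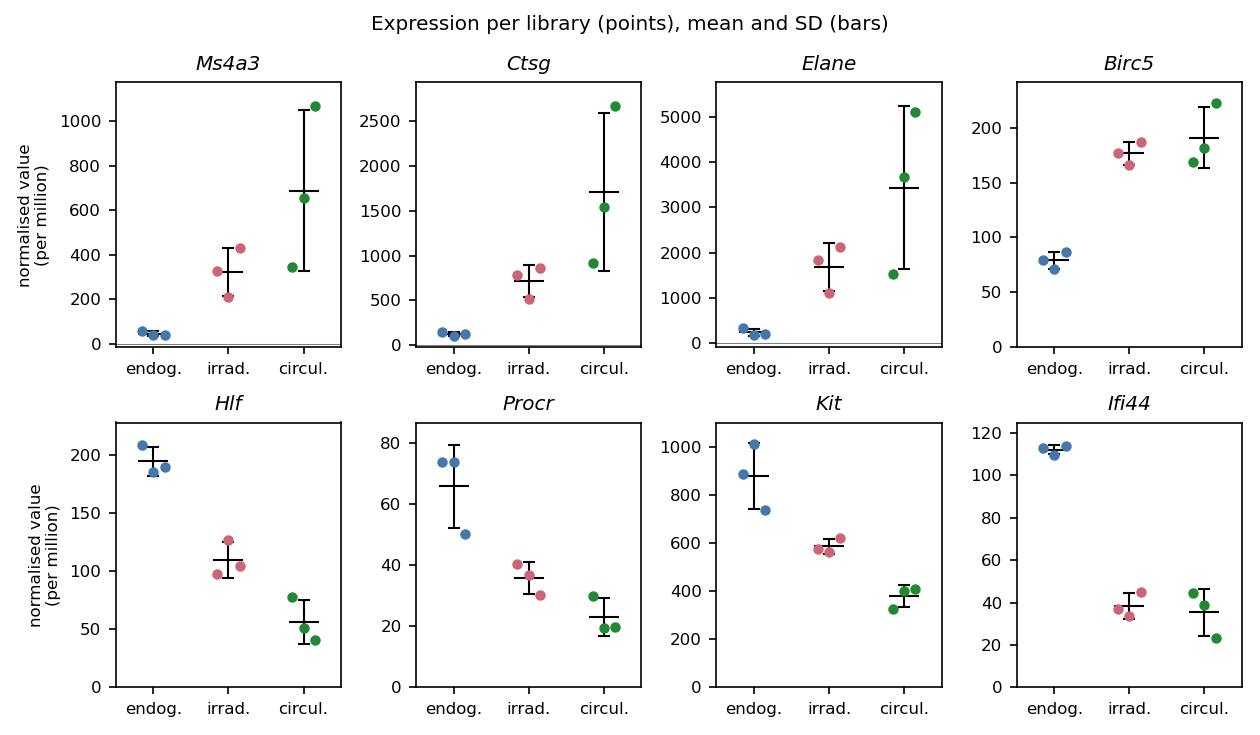
Normalised values (linear vertical axis from 0) of 8 genes in endogenous, irradiated and circulating libraries; points are libraries, horizontal marks means and bars SD (n = 3). The mean of Ms4a3 was 46.8 in endogenous, 323 in irradiated and 688 in circulating cells, and that of Hlf was 195, 110 and 56.5.

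Of the lists of other cell types, the B lineage, mast cell and neutrophil lists were called between circulating and endogenous cells. Those of T cells (camera adjusted p = 0.28), NK cells (0.056), dendritic cells (0.096), monocytes (0.30), plasma cells (0.16), erythroid cells (0.12) and endothelial cells (0.096) were not. Cd79a, a component of the B cell receptor, was 44.9 ± 23.7 in circulating and 7.70 ± 4.80 in endogenous cells (log2 fold change 2.37, SE 0.54, limma adjusted p = 0.0262). Of 11 B lineage genes, 2 rose and 9 did not pass, also when adjusted over the list alone (median 0.60, camera adjusted p = 0.020, and adjusted p = 0.46 with an estimated correlation). Of 7 MHC class II genes, 4 rose and 3 did not pass, with 5 rising when adjusted over the list alone (median 1.85, camera adjusted p = 0.00049, and adjusted p = 0.41 with an estimated correlation). Xcr1, a marker from the uncalled dendritic list, was 57.6 ± 52.4 against 5.86 ± 2.52, and 2 of the 8 genes of that list passed. Hdc, expressed in mast cells and basophils, was 106 ± 64.0 against 13.1 ± 2.21 and was the 1 of 7 genes of its list that passed, with 2 rising when adjusted over the list alone (median 1.66, camera adjusted p = 0.0021, and adjusted p = 0.41 with an estimated correlation). Neutrophil markers went the other way: 2 of 13 fell, 0 rose and 11 did not pass, with 3 falling when adjusted over the list alone (median -0.91, camera adjusted p = 0.017, and adjusted p = 0.43 with an estimated correlation). Mmp8, a neutrophil granule collagenase, was 11.7 ± 8.27 against 70.4 ± 21.9. The B lineage call ended without circulating replicate 2 (adjusted p = 0.10), circulating replicate 3 (0.081) or endogenous replicate 2 (0.061) and with camera on voom weights (0.12), and the neutrophil call without circulating replicate 3 (0.072) or endogenous replicate 1 (0.085).

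Across all tested genes, 1189 of 13771 were called, 734 higher and 455 lower in circulating cells. The groups did not overlap in 3786 genes (27.5%, where chance gives 10%), and 3672 genes had an unadjusted p under 0.05, where 689 would be expected by chance. The largest rises by the fixed rule were Cldn15 (139 ± 72.0 against 5.97 ± 1.81, on chromosome 5 from 136966616 to 136975858), Ms4a3, Elane, Dmkn, Ctsg, Fcgr3, Sgms2, Kel, Trem3 and Prom1. The largest falls were Abcg3 (4.10 ± 6.21 against 38.3 ± 11.6), Ndn, Pdgfd, Sema3d, Npdc1, Axl, Mmp8, Tle2, Nap1l3 and Bgn. The count depends on how spread is shared: 494 genes were called with sample weights and 239 when only these 2 groups were fitted, and in simulations with the spread of each group 10.9% of calls were false. It was 2224 without circulating replicate 1, 532 without circulating replicate 3, 622, 698 and 645 without irradiated replicates 1, 2 and 3, and 257, 302 and 486 without endogenous replicates 1, 2 and 3. Of 91 named calls, between 5 (without circulating replicate 1) and 45 (without endogenous replicate 1) were lost. Scaling by library size alone shifted the median gene by -0.22 log2 units and gave 340 higher and 821 lower calls.

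**Figure D2:**
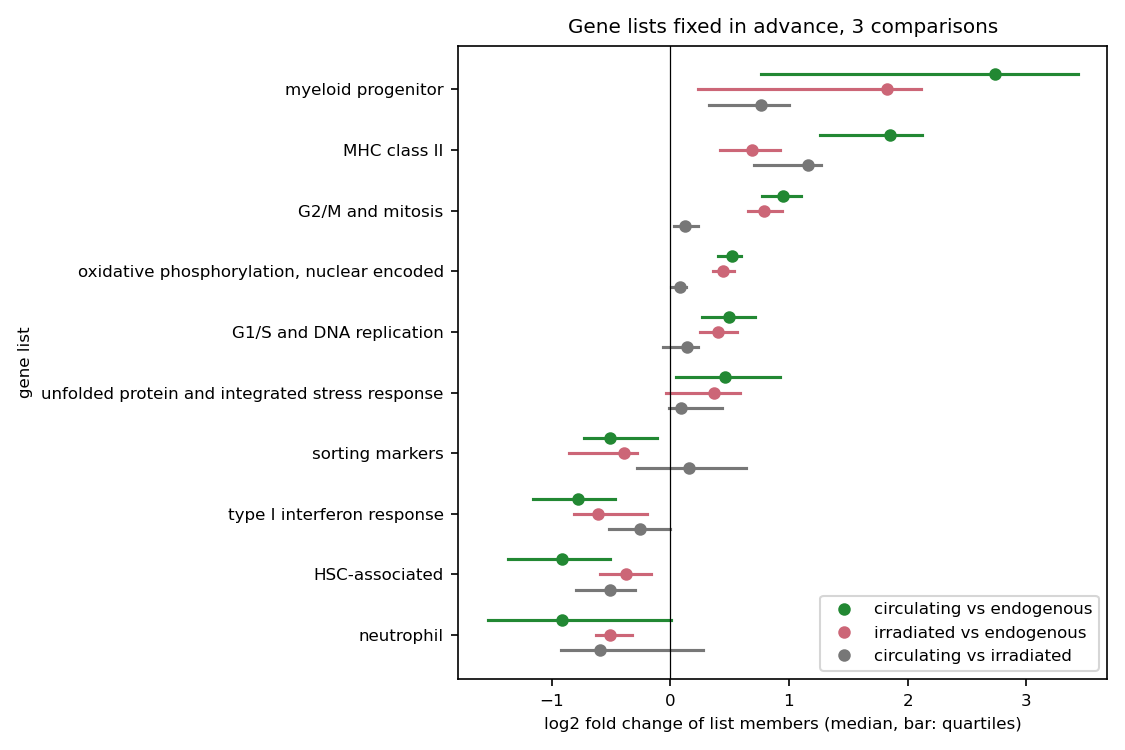
Log2 fold changes (horizontal axis) of 10 gene lists in 3 comparisons; points are medians over list members and bars run from the lower to the upper quartile. The myeloid progenitor median was 2.74 for circulating and 1.83 for irradiated against endogenous cells, and the HSC-associated median -0.91 and -0.37.

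Irradiated LSK cells were then compared with endogenous LSK cells. At the preset correlation the myeloid progenitor and mitosis lists were called higher and the interferon list lower in irradiated cells, but most of their members did not pass singly and none of the 3 lists was called with an estimated correlation. Of 17 myeloid progenitor genes, 5 rose and 12 did not pass, with 11 rising when adjusted over the list alone (median 1.83, camera adjusted p = 2.2e-10, and adjusted p = 0.28 with an estimated correlation). Ms4a3 was 323 ± 109 against 46.8 ± 10.1 (log2 fold change 2.72, SE 0.36, limma adjusted p = 0.00998) and Ctsg 719 ± 181 against 125.0 ± 20.4. Of 24 genes of G2/M and mitosis, 4 rose and 20 did not pass, with 23 rising when adjusted over the list alone (median 0.79, camera adjusted p = 9.6e-23, and adjusted p = 0.19 with an estimated correlation). These were Birc5 at 177 ± 10.4, Ccnb2 at 258 ± 25.4, Cdc20 at 250.4 ± 36.8 and Cdk1 at 232 ± 34.6, against 79.3 ± 7.80, 140 ± 5.25, 122 ± 7.32 and 128 ± 11.9 in endogenous cells. Of 30 type I interferon genes, 2 fell and 28 did not pass, with 10 falling when adjusted over the list alone (median -0.60, camera adjusted p = 5.7e-08, and adjusted p = 0.16 with an estimated correlation): Ifi44 was 38.4 ± 5.92 and Irf9 115 ± 3.80. Of 21 HSC-associated genes, 1 fell and 20 did not pass, with 4 falling when adjusted over the list alone (median -0.37, camera adjusted p = 0.00034, and adjusted p = 0.13 with an estimated correlation). Respiratory chain genes were higher as a list (median 0.45 over 35 genes, camera adjusted p = 3.9e-21, and adjusted p = 0.16 with an estimated correlation): 2 rose and 33 did not pass, with 27 rising when adjusted over the list alone.

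Other lists were lower in irradiated than in endogenous cells with 0 members called singly. Sorting markers had a median of -0.39 over 10 genes, with 4 falling when adjusted over the list alone (camera adjusted p = 0.00038, and adjusted p = 0.23 with an estimated correlation). Genes of NF-kB and inflammatory signalling had a median of -0.35 over 16 genes, with 1 falling when adjusted over the list alone (camera adjusted p = 0.0065, and 0.28 with an estimated correlation). Neutrophil markers had a median of -0.51 over 13 genes, with 0 when adjusted over the list alone (camera adjusted p = 0.038, and 0.64 with an estimated correlation). That call ended without irradiated replicate 3 (0.43) or endogenous replicate 1 (0.27), and when scaled by library size alone (0.079). Mitochondrially encoded genes had a median of -0.16 over 13 genes, with 0 when adjusted over the list alone (camera adjusted p = 0.037, and 0.66 with an estimated correlation). That call ended without irradiated replicate 3 (0.23), endogenous replicate 2 (0.32) or endogenous replicate 3 (0.099), and with GC content and length trends removed (0.066).

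Lists called higher in irradiated than in endogenous cells, beside those above, were cytosolic ribosomal proteins (median 0.253, camera adjusted p = 5.3e-12), G1/S (0.40, 3.5e-11), unfolded protein response (0.37, 0.0027), NRF2 targets (0.327, 0.0056), ribosome biogenesis and MYC targets (0.212, 0.007), glycolysis (0.274, 0.028), MHC class II (0.691, 0.036) and megakaryocyte and platelet genes (0.588, 0.048). Of their members, 2 of 26 G1/S genes and 2 of 21 glycolysis genes rose, 1 of 13 megakaryocyte genes rose and 1 fell, and no others passed. None was called with an estimated correlation (adjusted p from 0.13 to 0.64). The MYC target call ended without irradiated replicate 3 (0.16). The glycolysis call ended without irradiated replicate 3 (0.12), endogenous replicate 3 (0.20) or circulating replicate 2 (0.053), the MHC class II call without irradiated replicate 1 (0.091) or 2 (0.13) or endogenous replicate 3 (0.16), and the megakaryocyte call without irradiated replicate 2 (0.061) or 3 (0.12) or endogenous replicate 3 (0.32). With GC content and length trends removed these 3 also ended (0.063, 0.064 and 0.065), as did MHC class II with camera on voom weights (0.055) and the megakaryocyte list with the replicate number as a block (0.07).

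The comparison called 83 genes, 65 higher and 18 lower in irradiated cells. The groups did not overlap in 3815 genes (27.7%, where chance gives 10%), and 2053 genes had an unadjusted p under 0.05, where 689 would be expected by chance. Among them was Selp, which encodes the adhesion molecule P-selectin, at 130 ± 15.3 against 23.4 ± 5.80 (log2 fold change 2.45, SE 0.33, limma adjusted p = 0.00998). Fn3krp, which encodes a kinase that repairs glycated proteins, had the largest rise at 39.4 ± 3.88 against 0.517 ± 0.135. The largest fall was in Ctse, which encodes the aspartic protease cathepsin E, at 61.5 ± 15.2 against 759 ± 63.3 (log2 fold change -3.63, SE 0.18, limma adjusted p = 4.3e-06). The chemokine receptor gene Cxcr4 was 10.96 ± 3.11 against 47.3 ± 3.33 and also fell, as did Dynlt1b, a dynein light chain gene, at 20.7 ± 1.39 against 200 ± 24.8. Dynlt1b has near-identical copies between which reads cannot be assigned with certainty. Of 27 p53 target genes, 0 passed (median 0.25, camera adjusted p = 0.24), among them Bax at 64.0 ± 2.24 against 43.8 ± 3.26. The count was 897 with sample weights and 757 when only these 2 groups were fitted. Circulating against endogenous gave 494 and 239 in the same fits, so the order of the 2 comparisons reversed. In simulations with the spread of each group, 0% of this comparison's calls were false and 44.3% of 2-fold changes were recovered. With sample weights these were 5.46% and 60.8%. The count of 83 thus does not show a smaller difference than the 1189 calls of circulating against endogenous, and it rested on each library. It was 263, 137 and 235 without circulating replicates 1, 2 and 3, 7, 32 and 6 without irradiated replicates 1, 2 and 3, and 6, 7 and 27 without endogenous replicates 1, 2 and 3. Of 35 named calls, 31 were lost without irradiated replicate 3 or without endogenous replicate 1 or 2, and 30 without irradiated replicate 1. Scaling by library size alone gave 51 higher and 27 lower calls, with the median gene at -0.13 log2 units.

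Both of these comparisons used the same 3 endogenous libraries. Of their calls, 56 were higher in both and 8 lower in both, where independent lists would share 3.5 and 0.59 and simulated unchanged groups shared 0 and 0. The log2 fold changes correlated across genes at r = 0.637 (simulated 0.402), with a covariance of 0.208 against 0.0572 simulated, a difference of 0.151. Over 100 simulations of unchanged groups with shared controls the highest values were r = 0.436 and a covariance of 0.0655. These simulations drew noise independently for each gene, without genes that move together in a library. Their range is therefore too narrow to decide whether shared controls alone gave this correlation. Unchanged groups give almost no calls, so their 0 shared calls say nothing about the overlap of calls. Genes are not independent replicates, and 3 control libraries are too few to split, so part or all of the excess may come from them.

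Circulating and irradiated LSK cells differed in 4 genes of 13771. They carry the same strain label, but whether the circulating cells are of that strain stays open. At an unadjusted p under 0.05 there were 1573 genes, where 689 would be expected by chance. The groups did not overlap in 2303 genes (16.7%, where chance gives 10%), and limma-voom called 8 genes. With the replicate number as a block 9 genes were called, 6 higher and 3 lower, and with a block by the code in the titles 5, 4 higher and 1 lower, and all 4 genes were kept in both. Ctse was 623 ± 105 in circulating and 61.5 ± 15.2 in irradiated cells (log2 fold change 3.33, SE 0.18, limma adjusted p = 7.82e-06). Dynlt1b was 198 ± 38.2 against 20.7 ± 1.39, with the same uncertainty about its copies. Cxcr4, the receptor that holds stem cells in the marrow, was 62.8 ± 4.32 against 10.96 ± 3.11 (log2 fold change 2.44, SE 0.22, limma adjusted p = 0.000961). Adgrg1, an adhesion receptor gene of stem cells, was the only call lower in circulating cells, at 627 ± 94.8 against 1214 ± 26.9 (limma adjusted p = 0.0298). Its call ended without irradiated replicate 1 (adjusted p = 0.158), 2 (0.142) or 3 (0.256) without endogenous replicate 1 (0.0563) or 2 (0.0615), with no robust moderation (0.051) and when only these 2 groups were fitted (0.0894). The count was 137, 7 and 9 without circulating replicates 1, 2 and 3, and 11 with scaling by library size alone, of which 3 were higher and 8 lower. Ctse lies on chromosome 1 from 131638306 to 131675505 and Cxcr4 from 128588199 to 128592293, and Ptprc, whose alleles define the CD45.1 strain, from 138062861 to 138175708. With genes within 20 Mb of Ptprc left out, only Dynlt1b was called. Ctse and Cxcr4 lie in the omitted interval. Adgrg1 lies on chromosome 8 from 94974751 to 95014217, and its log2 fold change stayed at -0.964 while its adjusted p became 0.0591. Cxcr2, a receptor for the chemokine CXCL1, was 20.1 ± 8.93 in circulating, 12.0 ± 1.15 in irradiated and 22.1 ± 4.32 in endogenous cells and passed no pairwise test.

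**Figure D3:**
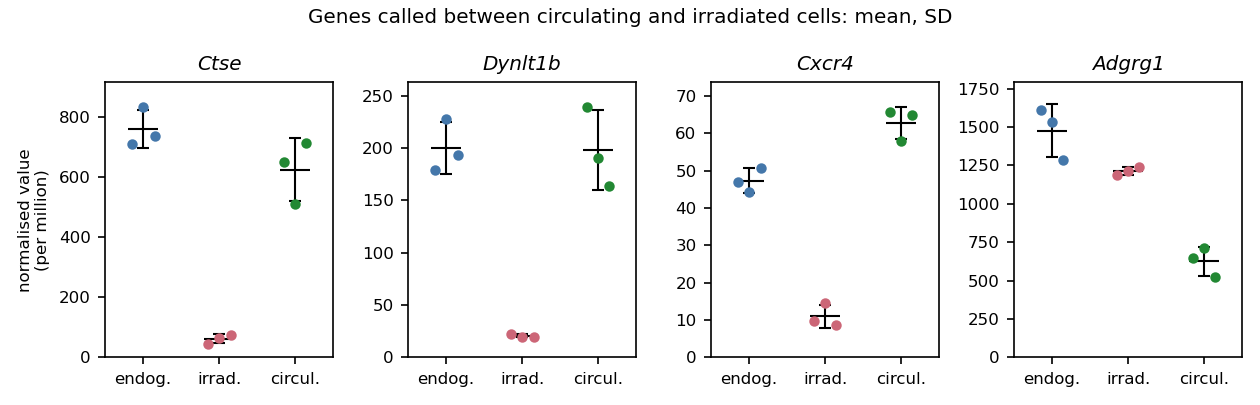
Normalised values (linear vertical axis from 0) of the 4 genes called between circulating and irradiated cells; points are libraries, horizontal marks means and bars SD (n = 3). Ctse, Dynlt1b and Cxcr4 were low in irradiated libraries alone, with Cxcr4 at 62.8 in circulating, 47.3 in endogenous and 10.96 in irradiated cells.

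Among gene lists, HSC-associated genes were lower in circulating than in irradiated cells (median -0.51 over 21 genes, camera adjusted p = 1.3e-05, and adjusted p = 0.092 with an estimated correlation), although 0 of them were called singly and 2 fell when adjusted over the list alone. Hlf was 56.5 ± 19.0 in circulating and 110 ± 15.4 in irradiated cells. Megakaryocyte and platelet genes were lower too (median -0.91 over 13 genes, camera adjusted p = 1.8e-05, and adjusted p = 0.55 with an estimated correlation), with 0 called singly and 5 falling when adjusted over the list alone. Their mean log2 level in circulating replicate 2 (4.334) lay within the irradiated range (4.312 to 4.606). Circulating replicates 1 (2.794) and 3 (3.626) lay below it. Selp was 40.3 ± 19.8 against 130 ± 15.3. The myeloid progenitor list was higher (median 0.77 over 17 genes, camera adjusted p = 2.8e-06, and adjusted p = 0.55 with an estimated correlation) with 0 called singly and 0 when adjusted over the list alone. The list's mean log2 level in circulating replicate 1 (7.308) lay within the irradiated range (6.951 to 7.58). Only circulating replicates 2 (8.287) and 3 (8.571) lay above it. Beside these shifts, T cell markers were higher (median 1.38 over 10 genes, camera adjusted p = 0.0027, and adjusted p = 0.55 with an estimated correlation), as were mast cell and basophil markers (median 1.20 over 7 genes, camera adjusted p = 0.0065, and adjusted p = 0.55 with an estimated correlation). The T cell call ended without circulating replicate 2 (median 0.295, adjusted p = 0.25), and the mast cell call without circulating replicate 2 (median 0.88, adjusted p = 0.085) or 3 (median 0.38, adjusted p = 0.21) and with camera on voom weights (0.061).

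Other lists were called between circulating and irradiated cells at the preset correlation, with 0 members called singly. Dendritic cell markers (median 0.855, camera adjusted p = 0.014), monocyte and macrophage markers (0.341, 0.018), MHC class II genes (1.163, 0.0039), B lineage genes (0.35, 0.046), NK cell markers (0.678, 0.046), plasma cell genes (1.347, 0.046) and erythroid genes (0.427, 0.046) were higher in circulating cells. So were mitochondrially encoded genes (0.195, 0.018), G2/M genes (0.123, 0.018) and G1/S genes (0.139, 0.046), and interferon genes were lower (-0.254, 0.016). With an estimated correlation, adjusted p was 0.55 or 0.68 for each of them. The dendritic call ended without circulating replicate 2 (0.16), as did MHC class II (0.085), and the monocyte call without circulating replicate 2 (0.074) or 3 (0.28) and with camera on voom weights (0.073). The B lineage call also ended with the replicate number as a block (0.089) and with the block by title code (0.086). The B lineage, NK, plasma and erythroid calls each ended in 5 or more of the 9 fits that left out 1 library, among them those without circulating replicate 3 (0.22, 0.13, 0.21 and 0.86) and irradiated replicate 2 (0.10, 0.079, 0.19 and 0.13). All 4 also ended with RLE scaling (0.053 each), with camera on voom weights (0.18, 0.13, 0.13 and 0.084) and with GC content and length trends removed (0.059, 0.08, 0.059 and 0.059). The mitochondrially encoded call ended without circulating replicate 1 (0.60) or irradiated replicate 3 (0.15), and with GC content and length trends removed (0.23). The interferon call ended without circulating replicate 3 (0.26) or irradiated replicate 1 (0.055), the G2/M call without circulating replicate 1 (0.058) or 3 (0.97) or irradiated replicate 2 (0.38), and the G1/S call without circulating replicate 2 (0.24) or 3 (0.19) or irradiated replicate 1 (0.079) or 2 (0.11), when scaled by library size alone (0.095) and with GC content and length trends removed (0.057).

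**Figure D4:**
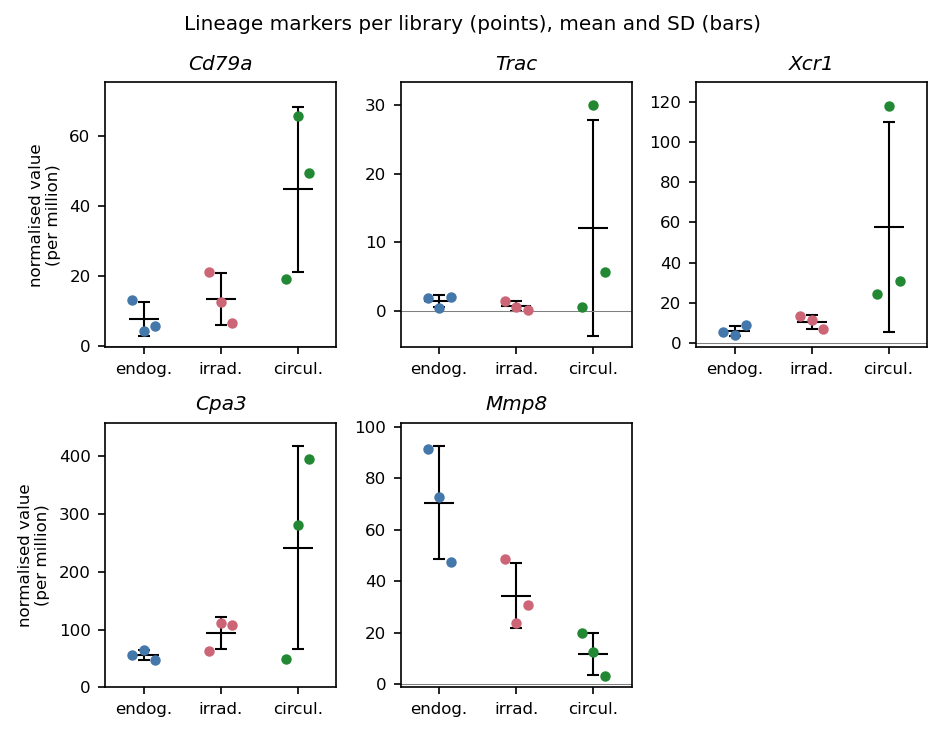
Normalised values (linear vertical axis from 0) of 5 lineage markers; points are libraries, horizontal marks means and bars SD (n = 3). Cd79a reached 65.8 in circulating replicate 2 and 49.7 in circulating replicate 3, and Trac 30.1 in circulating replicate 2.

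Circulating cells were last set against the mean of the other groups. The contrast called 349 genes, 191 higher and 158 lower. Among the largest rises by the fixed rule were Cd36 (36.5 ± 25.8 in circulating cells, 4.80 ± 0.795 in irradiated and 2.97 ± 0.959 in endogenous cells), Gpr141b, Dgat2 and Xcr1. The largest falls were Pdgfd (0.763 ± 0.629 against 7.47 ± 4.27 and 13.6 ± 6.50), Ndn, Bgn, Slc16a9 and Lhcgr. The HSC-associated list fell in 4 of 21 genes and 17 did not pass, with 12 falling when adjusted over the list alone (median -0.72, camera adjusted p = 5.7e-08), and it held with an estimated correlation (adjusted p = 0.041). The count was 41 with sample weights and 108 with limma-voom, and 20.3% of this contrast's calls were false in simulations with the spread of each group. It was 1439, 94 and 60 without circulating replicates 1, 2 and 3, 42, 38 and 67 without irradiated replicates 1, 2 and 3, and 68, 72 and 43 without endogenous replicates 1, 2 and 3. Of 10 named calls, 0, 6 and 4 were lost without circulating replicates 1, 2 and 3, 9, 7 and 5 without irradiated replicates 1, 2 and 3, and 4, 6 and 6 without endogenous replicates 1, 2 and 3. Scaling by library size alone gave 109 higher and 285 lower calls, with the median gene at -0.15 log2 units.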

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

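Pseudocounts, sample weights, thinning, trend removal, the block by title code and the omission of genes near Ptprc were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run, because the table holds normalised values. Pairing is open: circulating and irradiated libraries of the same number share a code in their titles, and the labels do not say what it stands for. Their residual correlations were 0.05, 0.031 and 0.18 for numbers 1, 2 and 3. Over all groups, residual correlations of same-numbered libraries ran from -0.023 to 0.18, and 6 of 9 libraries correlated best with their own number. No chance level was worked out for this count, so it does not decide whether libraries were paired. With the replicate number as a block, the counts were 1147, 9, 105 and 240 for circulating against endogenous, circulating against irradiated, irradiated against endogenous and the contrast with the mean, and 1469, 5, 205 and 595 with the block by title code. For gene lists the blocks gave 15, 15, 17 and 19, and 18, 15, 20 and 19. In the same order, limma-voom with sample quality weights gave 376, 4, 772 and 25 genes, sample weights 494, 4, 897 and 41, and limma-voom 834, 8, 94 and 108. Testing against a fold of 1.5, a stricter question by construction, left 23, 3, 5 and 0. Fits of only the groups compared gave 239, 4 and 757. The contrast with the mean gave 193 genes with no pseudocount. Circulating against irradiated gave 11 genes scaled by library size alone (3 higher, 8 lower), 7 when thinned, 9 with GC content and length trends removed (3 higher, 6 lower) and 1 without genes near Ptprc. The last follows by construction, because Ctse and Cxcr4 lie in the omitted interval, while Adgrg1 kept its fold with adjusted p at 0.0591. For thinning and trends the cause was not tested. Sharing one spread across groups that differ in spread explains the direction of the weighted counts in simulated data only. Leaving out 1 library gave 257 (without endogenous replicate 1) to 2224 (without circulating replicate 1), 3 to 137, 6 to 263, and 38 to 1439 genes. For gene lists, 15, 16, 17 and 18 were called, and leaving out 1 library gave 12 to 18, 7 to 16, 12 to 19 and 12 to 21. With an estimated correlation 1, 0, 0 and 1 lists were called, and with fry 9, 1, 5 and 8. Of the lists called at the preset correlation, fry called 7, 1, 5 and 6 in the same direction. The ribosomal protein list was called higher in circulating than in endogenous cells, with 2 of 77 genes rising (camera adjusted p = 2.8e-05). It was not called with an estimated correlation (adjusted p = 0.62). Scaled by library size alone, the list changed sign (median 0.18 to -0.02) and was no longer called. Over all alternatives, named genes kept their side of the threshold in 9740 cases, lost it in 809 and gained it in 183. No called value reversed. Most of the 9740 cases were genes not called in the main fit that stayed uncalled, so they do not measure how stable the calls were. Of 140 named calls over all comparisons, 5 were lost without circulating replicate 1 and 80 without endogenous replicate 1. These were the lowest and highest losses from leaving out 1 library, and the test against a fold of 1.5 lost more. Depth limits circulating replicate 2, where 560 genes had 0 counts.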

Other observations

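The tests of the interval around Ptprc by windows, of the stem cell, myeloid and mitosis lists and of the lineage markers were chosen after the results were seen; the list near Ptprc and the regrouping of libraries were planned. Glycolysis genes were also higher in circulating than in endogenous cells: 9 of 21 rose, 1 fell and 11 did not pass, with 10 rising and 5 falling when adjusted over the list alone (median 0.36, camera adjusted p = 0.017, and adjusted p = 0.41 with an estimated correlation). The call ended without endogenous replicate 3 (median 0.33, adjusted p = 0.072). Gapdh was 2684 ± 344 against 1737 ± 107 (SD, n = 3). Of 30 trafficking and adhesion genes, 3 rose, 2 fell and 25 did not pass, with 7 rising and 3 falling when adjusted over the list alone, and the list was not called (camera adjusted p = 0.69). The chemokine receptor gene Ccr2 rose to 185 ± 139 from 27.4 ± 5.25. Metallothionein Mt1 rose to 86.8 ± 48.9 from 10.4 ± 2.99. Ighg2c, named after its values were seen, was 8125 in circulating replicate 3 and 1.02 and 2.37 in the other circulating libraries, against 0.839 ± 0.208 in irradiated and 1.08 ± 0.224 in endogenous cells, and passed no test.

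Other splits of the libraries were compared with the real one. The real split called 1189 genes for circulating against endogenous cells, 4 for circulating against irradiated and 83 for irradiated against endogenous; the highest of the other 9 splits gave 1, 0 and 3. With 10 splits of 6 libraries, 1 of them the real one, a share under 0.05 cannot be reached. For the contrast with the mean, 3 of 100 partitions gave at least the real 349 genes, 1 of them the real one. The others, with 838 and 537 genes, set the endogenous libraries against the rest. The 838 genes came from the real groups with only the contrast changed, so this was no regrouping. Partitions that set libraries of different groups against the rest gave at most 2 genes. The number of calls also depends on the spread within groups, with a median SD of 0.262 log2 units in endogenous and 0.382 in circulating cells. It therefore does not rank the groups by how far apart they stand.

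Near Ptprc, the irradiated libraries showed an excess only relative to their own share elsewhere. Genes at p under 0.01 for irradiated against the mean of the other groups made up 16 of 208 genes (7.69%) within 20 Mb of Ptprc. They made up 1.76% of genes elsewhere (one-sided Fisher exact p = 1.63e-06). For circulating cells the shares were 9.62% near Ptprc and 8.78% elsewhere (one-sided Fisher exact p = 0.371). For endogenous cells they were 13% and 11.2% (one-sided Fisher exact p = 0.238). The irradiated share near Ptprc was thus lower than that of either other group. For irradiated cells, the bin of chromosome 1 from 120 to 140 Mb ranked 1 of 133, with 11.9% of its genes against 5.88% in the next bin. Ctse and Cxcr4, already called when the windows were chosen, lie in this bin and count among the 16 genes. The ranking therefore cannot decide whether the response of the irradiated cells was spread over the genome without regard to this interval. The planned list of genes near Ptprc did not decide it either. Its one-sided Fisher exact p was 0.0104 for circulating against irradiated, where 1 of 36 members was among the 4 genes called. It was 0.196 for irradiated against endogenous and 0.83 for circulating against endogenous. A candidate explanation, as a hypothesis, is that cells labelled circulating carry the CD45.1 interval like the endogenous group, so that the Ctse and Cxcr4 differences may reflect strain alleles; a local response of these genes to irradiation stays open, and no variants were analysed here. The titles give circulating and endogenous libraries the code LSK1 and irradiated libraries LSK2, and since its meaning is not stated, whatever it marks cannot be separated from the irradiated group.

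Lower stem cell genes with higher myeloid and mitosis genes, circulating against endogenous, were weighed against technical causes. With GC content and length trends removed the HSC-associated median was -0.843, and with counts thinned to the total of the shallowest library it was -0.96, with the myeloid and mitosis lists also still called, so neither these trends nor the count totals are likely to be the whole cause, although thinning matches totals only and not the number of molecules captured. Mature neutrophils are unlikely as the main source of the myeloid genes, since the neutrophil list had a median of -0.914 (SD of its members 1.36), while the myeloid median was 2.74. That fall is itself uncertain: 2 of 13 genes passed, adjusted p was 0.43 with an estimated correlation, and the call ended without circulating replicate 3 (0.072) or endogenous replicate 1 (0.085). Myeloid progenitors at the edge of the sorting gates, the strain label, and a difference between the cells the labels name stay open. None of them was tested.

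Lists of B, T, plasma, dendritic and mast cell markers were called higher in circulating than in irradiated cells at the preset correlation, with 0 members called singly, and none of them with an estimated correlation (adjusted p from 0.55 to 0.68). In circulating replicate 1 the mean log2 level of mast cell (3.022) and B lineage markers (4.265) lay below every irradiated library, that of T (1.555) and dendritic markers (4.622) within the irradiated range, and only that of plasma cell markers (5.599) above it. Against endogenous cells the T (camera adjusted p = 0.28), plasma (0.16) and dendritic (0.096) lists were not called. Circulating replicate 2 also stood out in the sex-linked transcript Xist, at 14.54. In the other libraries Xist ran from 0.1246 to 1.905. Ddx3y, on the Y chromosome, was 89.3 in circulating replicate 2. What the Xist value marks was not tested. A lower share of LSK cells raising every other cell type alike cannot be told apart from a change in these cells: the lists were chosen after their direction was seen, and the neutrophil list, with a median of -0.594, was not called (camera adjusted p = 0.20). Carry-over of mature B cells, which the lineage gate should remove, cannot be told apart from lymphoid transcripts of the LSK cells either: Ighm ranked 9 of 9 in circulating replicate 2, at 581, but it was high in every group and reached 22640 in irradiated replicate 1.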
